A study of Escherichia coli with 4 samples.

How the data were processed

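Messenger RNA and ribosome-protected fragments (RPFs) were sequenced from 2 strains of Escherichia coli K-12, giving 4 libraries with 1 library per group. The wild type was MG1693, a thymine-requiring K-12 strain, and the hfq mutant was CMA540, in which hfq was replaced by a chloramphenicol resistance cassette. Per the labels' protocols, cultures grew in LB with 50 µg/ml thymine at 37 °C and were collected in exponential phase at an optical density (600 nm) of about 0.5. Total RNA was depleted of small RNAs and rRNA and broken into fragments of 24 to 35 nucleotides. For the RPF libraries, lysates were digested with micrococcal nuclease in a buffer with chloramphenicol, monosomes were separated on sucrose gradients, and fragments of 20 to 35 nucleotides were selected. An RPF is the stretch of mRNA that a ribosome shields from the nuclease. The RPF value of a gene therefore reflects the ribosomes on all copies of its mRNA, relative to the library total. Only its ratio to the mRNA value bears on ribosomes per mRNA.

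The deposited tables give 1 RPKM value (reads scaled to gene length and library total) per gene and library, as their column header states. Reads were trimmed with cutadapt 1.8.3, aligned with Bowtie 1.1.2 and counted with bedtools 2.17.0, per the submitters' processing notes. The genome build, the annotation, the handling of reads that map to several places and the use of strand are not given in the sources used here. Each table held 4418 entries in the same order. Every file had 1 line that held 2 entries run together, which were split at the next gene identifier, and the wild-type RPF table also had 1 blank line. The 18 entries with a placeholder in place of a gene name were left out. They held 0.00545% of the summed RPKM in wild-type mRNA, 0.0199% in mutant mRNA, 0.00111% in wild-type RPF and 0.0145% in mutant RPF.

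Gene lengths came from a RefSeq gene table of assembly ASM584v2, used for names, lengths and the order of genes only. Of the entries, 3997 matched it by symbol, 233 by a synonym and 188 not at all. RPKM multiplied by gene length was a whole multiple of 1 step per library, within 0.01 read, for 97.0% of the values above 0 in wild-type mRNA, 97.1% in mutant mRNA, 97.3% in wild-type RPF and 97.5% in mutant RPF. From these steps the read totals behind the RPKM were 17181779, 7836430, 788652 and 470060 in the same order. Whole reads were recovered in all 4 libraries for 4104 entries. The median entry had 115 reads in wild-type mRNA, 117 in mutant mRNA, 2 in wild-type RPF and 2 in mutant RPF, so single-gene RPF values are far less precise than mRNA values. Exact (Clopper-Pearson) 95% intervals were computed from these reads. They cover counting error only, since PCR copies are not independent molecules. Where a library had 0 reads, ratios were bounded with a floor of 3 reads per library. This bound takes the reads of the other library as exact, so the lower end of the exact interval is given beside it for RPF ratios.

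Many values appeared to stand under a neighbouring gene's name. The tables lack 3 genes of insertion elements that ASM584v2 has (insA9 and insB9 inside crl, and insH21). The crl value did not give whole reads at the 1178 bases of the reference. Among lengths up to that of the reference without the first element, the longest that gave whole reads was 402 bases, a gap of 776, and the shortest was 201. Longer lengths were left out of this choice, so the gap takes the absence of the first element as given. Intervals beyond the first element were placed 776 bases upstream of the named gene, and intervals beyond insH21 2000 bases upstream. The 229 whole-read entries before the first element kept their names, 927 lay between the elements and 2948 beyond. Each interval was therefore also assigned to the gene its displaced position lies on. A gene's reads were summed over the intervals with at least 50% of their length on it, giving 2573 position-matched genes. This assignment was chosen after the data were examined. Beyond insH21, wild-type mRNA values had a correlation of 0.280 with the overlap of the named genes with 164 genes known to be abundant, of 0.343 at 2000 bases and of at most 0.351, at 1500 bases. Between the elements the correlations were 0.217 by name, 0.230 at 776 bases and at most 0.258, at 400 bases. The displacement of 2000 bases was read from the data and rounded, and strand was not used. When a displacement was chosen on alternate blocks of 50 intervals beyond insH21 and scored on the blocks left out, it came to 700 and 1700 bases. The gain in correlation over the named genes was then 0.0401 (bootstrap over 59 blocks -0.00119 to 0.0900), an interval that includes 0. In the text a gene is named by its displaced position, with the deposited name beside it where an interval is first given.

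Log2 ratios of the mutant to the wild type used RPKM with a pseudocount of 1, which draws in ratios of low genes. In RPFs, however, 1 read per kilobase was worth 1.27 RPKM in the wild type and 2.13 in the mutant. Where a library had 0 RPF reads, the ratio can therefore exceed what the reads bear out, as for cstA (463-fold, with a floor bound of 24.0-fold). The mRNA and RPF comparisons kept entries with a mean of at least 5 RPKM over the compared libraries, and translation efficiency (the RPF value over the mRNA value) required this in both assays. Entries past a 2-fold difference were counted. With 1 library per group no test across samples was possible and no p-value is given, so no difference has a replicate check. Named genes followed a rule fixed before the data were examined: for each comparison the 12 entries of highest and the 12 of lowest log2 ratio with a mean of at least 50 RPKM over its libraries, hfq with its neighbours, and up to 3 highest and 3 lowest members of each described list. For 37 gene lists fixed at the same time, the median log2 ratio was placed as a percentile among 10000 random lists of the same size matched on mean expression in 20 bins. Lists needed 5 measured members. Bootstrap intervals of medians resampled list members, which are not independent where they share an operon.

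The comparisons were repeated with median-of-ratios scaling, totals without the 20 highest intervals, no filter, a minimum of 20 RPKM, pseudocounts of 10 and 0.2, a 3-fold threshold and 10 expression bins. After the data were examined, totals without tRNA, rRNA and abundant small stable RNA intervals (overlap of at least 20 bases), a filter of 64 reads per assay, displacements of 1800 and 2200 bases and an overlap of 80% were added.

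The steps were tested on simulated data. In 4104 simulated entries with mRNA changed 4-fold, 98 of 98 tested changes were recovered, and 2 of 2357 unchanged entries passed the 2-fold threshold. With RPFs changed 4-fold, 90 of 94 were recovered, and 180 of 1849 unchanged entries passed it. For translation efficiency with changed RPFs, 90 of 94 were recovered at 4-fold and 174 of 1794 unchanged entries passed. When reads were simulated on displaced intervals, true and estimated log2 ratios had a correlation of 0.888 across 2503 position-matched genes and of 0.127 across 3968 entries taken by name. The same displacement placed and recovered these reads, without counting error. The contrast therefore says nothing about whether the deposited values are displaced. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.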

Results

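Hfq is an RNA-binding protein that helps small regulatory RNAs pair with their target mRNAs. The comparison asked how its loss bears on mRNA levels and on translation, with attention to the ribosome. Libraries of mRNA and of RPFs were made from exponentially growing wild-type E. coli and from an hfq deletion mutant, with 1 library in each of the 4 groups. The RPKM values rested on 17181779 reads in wild-type mRNA, 7836430 in mutant mRNA, 788652 in wild-type RPF and 470060 in mutant RPF. No group had a replicate, so every ratio below compares 2 libraries, and intervals cover counting error only. Genes are named by the displaced position of their interval, with the deposited name given as "listed as". The displacement was read from the data and is uncertain. Values of intervals that span 2 genes are given under both names.

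The hfq region was examined in every library first. The interval listed as hflK had 1523 RPKM in wild-type mRNA and 85.8 in mutant mRNA. At the displacement used, this interval lies on the end of miaA (13.1% of its length), all of hfq (24.5%) and the start of hflX (49.7%). It held 32982 and 847 reads, a level 17.8-fold lower in the mutant (95% interval 16.6 to 19.0). Its RPF value was 1524 RPKM in the wild type and 11.8 in the mutant, from 1514 and 7 reads, or 129-fold lower (62.4 to 321). At the displacement used, the interval listed under the name hfq lies wholly on mutL, upstream of hfq, and then checks nothing about the deletion. It had 269 and 121 RPKM of mRNA, from 1430 and 292 reads, with 3 and 0 RPF reads. With names in place, these 292 mRNA reads would stand under hfq in the mutant that lacks it.

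The genes that follow hfq were also far lower in the mutant. The hflX and hflK interval (listed as hflC) was 39.4-fold lower in mRNA (34.1 to 45.8), hflK itself (listed as yjeT) was 43.9-fold lower (34.0 to 57.8) and the hflC and hflK interval (listed as purA) was 28.2-fold lower (25.5 to 31.3). HflX is a GTPase that acts on ribosomes, and HflK with HflC forms a membrane complex that regulates the FtsH protease. In RPFs the same 3 intervals were 71.8-fold (19.7 to 596), 31.8-fold (10.7 to 156) and 81.1-fold (39.2 to 202) lower. The interval after them on yjeT and hflC (listed as nsrR) was 14.0-fold lower in mRNA (11.0 to 18.2). On purA, nsrR and rnr (listed as rnr) the mutant was 2.03-fold lower in mRNA (1.99 to 2.07) and 3.52-fold lower in RPFs (3.18 to 3.89). Upstream, on miaA and mutL (listed as hflX), mRNA was 2.02-fold lower (1.96 to 2.09). Over the 9 measured neighbours the median log2 ratio was -1.01 in mRNA and -1.68 in RPF.

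**Figure D1:**
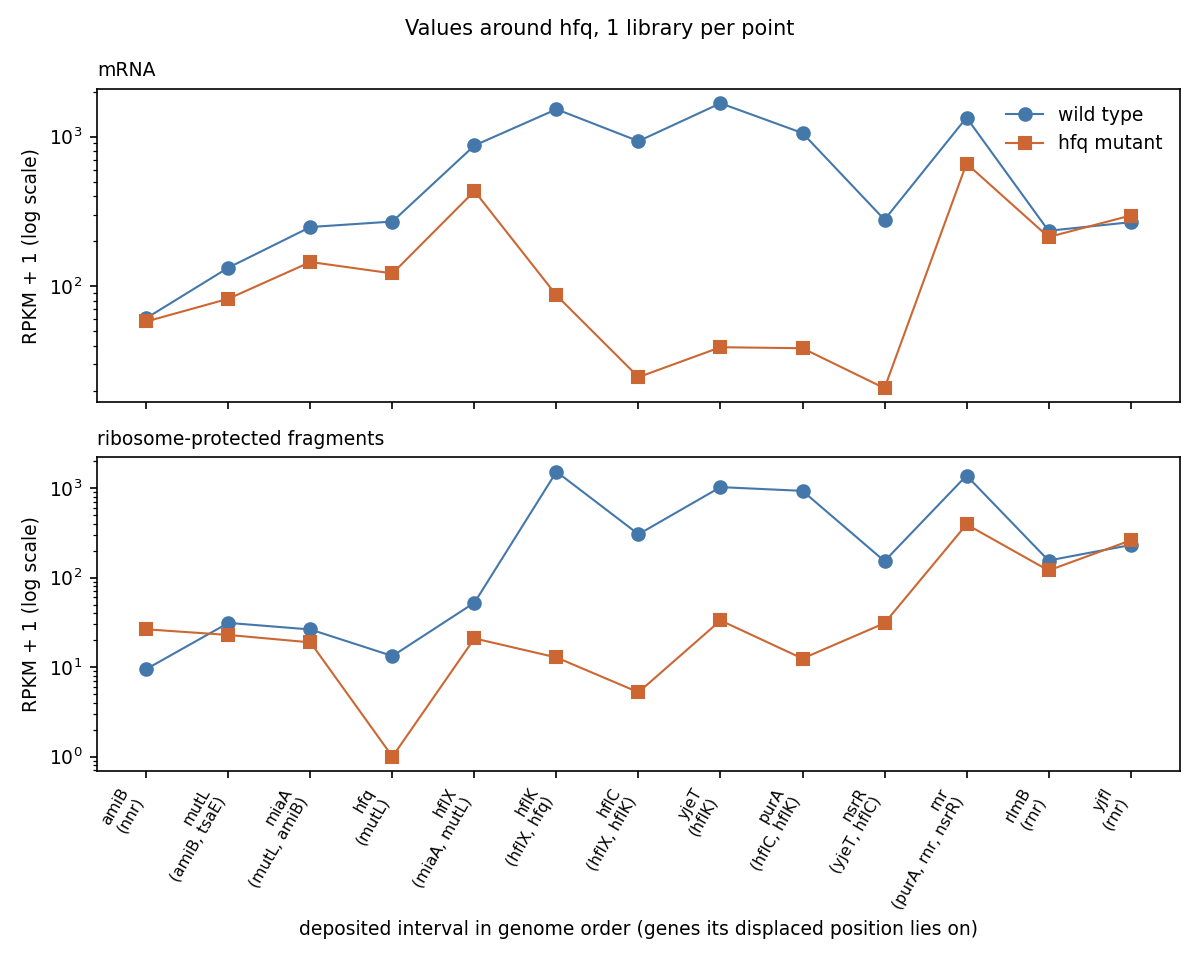
RPKM plus 1 (log scale) of mRNA (top) and RPFs (bottom) for deposited intervals in genome order around hfq, 1 library per point, wild type as circles and hfq mutant as squares; brackets give the genes an interval lies on. The mutant lies far below the wild type from the interval listed as hflK (1523 against 85.8 RPKM of mRNA), which holds hfq at the displacement used, to the hfl genes.

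In mRNA, the mutant stood far above the wild type for the chitoporin gene chiP and for most measured genes of the tricarboxylic acid (TCA) cycle, and far below it for nrdA and glp genes. The interval on chiP (listed as ybfN), the chitoporin gene known to be silenced by the small RNA ChiX, had 9.61 RPKM in the wild type and 3811 in the mutant, a 397-fold difference (304 to 528). Next came tnaB (listed as yidZ), the tryptophan permease beside tryptophanase, at 139-fold (117 to 165), and cstA (listed as ybdD), a starvation-induced transporter, at 103-fold (84.2 to 127). The arn operon, which modifies lipid A, took 4 of the 12 highest places in mRNA through intervals listed as arnA, arnD, arnT and arnC, with log2 ratios of 6.45, 6.43, 5.90 and 5.89, the last of them on ais next to it. The glycine cleavage genes gave 3 more, with log2 ratios of 6.12 and 5.98 on gcvP (listed as gcvH and gcvT) and a ratio between these on the interval listed as gcvP, which is spread over bglA, gcvP and ygfF. The other places went to aceA and aceB of the glyoxylate shunt (listed as aceK, 5.95) and oppA, the oligopeptide-binding protein and a known target of the small RNA GcvB (listed as oppC, 5.86).

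The lowest ratio in mRNA belonged to nrdA, the large subunit of aerobic ribonucleotide reductase (listed as nrdB, 2940 RPKM in the wild type and 51.6 in the mutant, 57.0-fold lower, 52.0 to 62.7), and a further interval on nrdA (listed as yfaE) had a log2 ratio of -5.60. The interval listed as nrdA had a log2 ratio of -4.91. It lies on yfaL for 57.1% of its length but also takes in part of nrdA, so its value cannot be assigned to yfaL. Glycerol uptake and anaerobic glycerol-3-phosphate genes were low too: glpA (listed as glpB, log2 ratio -5.78), glpF (listed as menA, -5.78), glpK with glpF (listed as rraA, -5.02), glpA with glpB (listed as glpC, -4.83) and glpK with glpX (listed as glpF, -4.37). The cysteine uptake gene cyuP (listed as tdcF) had -5.20. The other 3 of the 12 lowest were the hfl intervals.

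Among the lists fixed beforehand, 9 of 10 measured TCA cycle genes were at least 2-fold higher in mutant mRNA, with a median log2 ratio of 4.30 (bootstrap 3.40 to 4.59, percentile 99.9), 3.64 above the median of all matched genes. Examples were aceA at 5.95, acnA at 4.63, sdhA at 4.56 and acnB at 3.40, while lpd, which also serves pyruvate dehydrogenase, had -0.04. Amino acid and peptide transport genes had a median of 2.93 (0.69 to 3.46, percentile 100), with 21 of 37 at least 2-fold higher and 5 lower, but 1.07 by deposited names (24 of 45 higher, 6 lower). The genes tnaB, oppB and oppA had 6.95, 5.71 and 5.60, and tdcC, proV and dtpB had -2.41, -2.29 and -2.14. Tryptophanase and other amino acid catabolism genes had a median of 2.73 (percentile 100), with 9 of 15 higher and 3 lower, an interval from -0.20 to 5.11 and gcvP and gcvT at 6.02 and 5.46 after tnaB. With intervals lying at least 80% on their gene the median was below 0 (-0.23), and by deposited names it was 1.35 (13 of 24 higher, 5 lower). Flagellar genes were at low levels in both libraries, yet 25 of the 26 measured were at least 2-fold higher (median 2.56, percentile 100), as with flgB at 9 reads against 129. Only these 26 of 54 listed genes were measured. A gene very low in the wild type passes the filter on the mean only if it is high in the mutant, so the filter itself favours higher ratios here. Random lists matched on mean expression had a median of 1.09. Flagellar intervals held 0.00866% of wild-type and 0.0509% of mutant mRNA reads, but 0.00241% and 0.00234% of RPF reads (19 and 11 reads). Stress genes under RpoS, the general stress sigma factor, had a median of 2.10 (percentile 99.9) with 10 of 12 higher, led by osmY at 3.43 and yeaG at 3.41. The rpoS mRNA itself had 427 RPKM in the wild type and 2681 in the mutant.

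Genes reported in the literature as repressed by Hfq-dependent small RNAs had a median mRNA log2 ratio of 0.99 (-0.03 to 1.62, percentile 98.9), with 13 of 27 higher, 1 lower and 13 between. All position-matched genes had a median of 0.66 with 39.9% at least 2-fold higher, so much of this shift is shared by the whole library. The list lay 0.33 above that median. Among these targets, besides chiP and oppA, aldA had 5.13. Of the targets reported as activated, glmS, which makes glucosamine-6-phosphate and depends on the small RNA GlmZ, had 4625 RPKM in the wild type and 505 in the mutant, 9.15-fold lower (8.91 to 9.41), while rpoS and shiA had log2 ratios of 2.65 and 2.34. The activated targets had a median of 1.17 in mRNA (3 of 6 higher, 1 lower). In RPFs it was -1.57 (-3.99 to 2.04, 2 of 5 higher, 3 lower). In translation efficiency it was -1.45 (-2.98 to -0.31, 3 of 5 lower, none higher). Amino acid biosynthesis genes had a median of 1.12 (percentile 99.4, 28 of 55 higher and 9 lower), with sulphate assimilation genes cysI and cysC at 5.13 and 4.71 and ilvG at -4.00. Respiratory chain and ATP synthase genes went both ways (median 0.96, percentile 98.7): cyoE, cyoB and nuoG had 2.89, 2.75 and 1.96, and ndh, atpD and atpA had -2.92, -1.29 and -1.27. The 8 lists in the highest 2.5% in mRNA were also there when genes were taken by their deposited names, except that amino acid catabolism left this range with 10 expression bins (97.2).

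Large subunit ribosomal protein genes were lower in mutant mRNA, with a median log2 ratio of -1.55 (-1.75 to -1.32, percentile 0.14) and 10 of 11 at least 2-fold lower. Small subunit genes had -1.25 (-1.38 to -0.69), 7 of 10 lower, and a percentile of 13.6 (6.21 with 10 expression bins). By deposited names 17 of 29 large and 11 of 21 small subunit genes were at least 2-fold lower and 1 of each higher. Both lists were then in the lowest 2.5%, with 20 or 10 bins. Both stayed below 0 under each scaling tried. The lowest were rpsQ (listed as rpsS) at -1.91, rplD at -1.82 and rplP at -1.81, and the mildest was rpsA at -0.49. The 28 ribosomal protein intervals, which do not cover all listed genes, took 18.6% of wild-type mRNA reads (95% exact interval 18.6 to 18.6) and 7.34% of mutant mRNA reads (7.32 to 7.36), or 10.6% and 4.26% without the 20 highest intervals. Ribosome assembly factors had a median of 0.14, which turns negative with median-of-ratios scaling and without the 20 highest intervals; among them deaD had -2.52 and ysgA -4.04, the latter doubtful because its only interval (listed as rmuC) also covers part of udp. Genes for rRNA modification had -0.11 (percentile 6.59), tRNA modification enzymes -0.39 (percentile 2.82), aminoacyl-tRNA synthetases 0.02 (percentile 45.6, negative with the same 2 scalings) and translation factors -0.76 (percentile 8.63).

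Over all entries in mRNA, 2794 passed the filter, 1145 were at least 2-fold higher in the mutant and 362 lower, and the median log2 ratio was 0.69. Among the 2658 of them with recovered reads, 1075 were higher and 348 lower. Counting error alone gave at most 8 past 2-fold in any of 200 simulated draws. The split depends on the scaling: higher entries made up 76.0% of those past 2-fold, but 50.3% (674 higher and 666 lower) once that median was set to about 0. Small ratios are therefore not read as differences: lpd, for example, was above 0 (0.03) without the stable RNA intervals.

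In RPFs, the 12 highest log2 ratios included cstA (0 against 43 reads, at least 24.0-fold higher with the floor of 3 reads, 95% lower limit 18.7), srlA with srlE of sorbitol uptake (listed as srlD, 2 against 361 reads, 303-fold, 83.2 to 2510), chiP (3 against 372 reads, 208-fold, 70.6 to 1013) and the galactose uptake genes mglB with galS (listed as yeiB, 143-fold, 92.3 to 235) and mglA with mglB (listed as galS, 131-fold, 66.1 to 305). The glycolate oxidase genes had 0 wild-type reads, which makes glcD (listed as yghO) at least 61.0-fold and glcF with glcE (listed as glcD) at least 69.3-fold higher with the floor (lower limits 48.7 and 55.6). Tryptophanase tnaA with tnaB (listed as mdtL) was 136-fold higher, from 35 against 2836 reads. The other 4 were csdA (listed as tcdA, at least 29.6-fold with the floor, lower limit 23.3), ymgA with ycgZ (listed as ymgC, at least 9.51-fold with the floor, lower limit 6.92), recN with nadK (listed as bamE, 178-fold from 1 against 106 reads, 31.2 to 7090) and the prophage interval on ymfI and ymfJ (listed as ymfK, 153-fold from 3 against 274 reads, 51.9 to 748).

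The lowest RPF ratios were at hfq and hflX (129-fold), the hfl intervals, nrdA (53.1-fold lower, 39.0 to 74.1) and its partner nrdB (listed as yfaH, 38.0-fold, 17.3 to 104). Also among them were rapA (listed as hepA, an RNA polymerase recycling factor, 50.8-fold, 31.2 to 89.1), epmA with frdA (listed as yjeM, 78.7-fold from 132 against 1 reads, 13.9 to 3131), glpK with glpF (29.5-fold, 19.2 to 47.9) and glmU with glmS (listed as atpC, 25.1-fold, 18.3 to 35.2). The interval listed as nrdA, on yfaL and part of nrdA, was 27.8-fold lower (17.3 to 48.0).

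Ribosomal protein genes were lower in mutant RPFs. Position matching measured 11 of the 33 listed large subunit genes and 10 of the 21 small subunit genes. All 11 large (median -2.73, -3.08 to -2.32, percentile 1.20) and all 10 small subunit genes (median -2.59, -2.96 to -1.96, percentile 4.83) were at least 2-fold lower. The lowest were rpsQ at -4.13, rplK at -3.57 and rpsC at -3.19, and the mildest rpsT at -1.84. By deposited names 22 of 24 large and 16 of 17 small subunit genes were at least 2-fold lower and none higher. The 28 ribosomal protein intervals took 17.2% of wild-type RPF reads (17.1 to 17.3) and 2.74% of mutant RPF reads (2.69 to 2.79), or 10.0% and 2.12% without the 20 highest intervals. Genes for rRNA modification had a median of -1.47 (percentile 0.315, 8 of 11 lower), with rsmB (55 against 3 reads, 10.9-fold lower, 3.55 to 54.6) and rluA (34 against 2 reads, 10.1-fold lower, 2.60 to 87.1) lowest, tRNA modification enzymes -1.33 (percentile 0.58, 11 of 19 lower), with mnmG at -4.01 and mnmE at -3.37, and purine and pyrimidine biosynthesis genes -1.20 (percentile 0.915, 13 of 23 lower and none higher). Taken by deposited names, the rRNA modification list had a median of -0.73 (8 of 21 lower, 4 higher) and was at percentile 3.80 and small subunit genes at 1.72.

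On the other side, TCA cycle genes had a median RPF log2 ratio of 3.35 (2.74 to 5.44, percentile 100), 9 of 10 higher, with aceA at 5.57, fumC at 5.51 and sdhA at 5.44. Genes of sugar uptake and use (without the maltose system) had a median of 2.09 (0.48 to 3.19, percentile 100), 19 of 31 higher and 4 lower. Among them srlA, mglA and srlE had 7.86, 6.68 and 5.69, against mtlD, fruA and fruB at -3.93, -3.71 and -2.94. Amino acid and peptide transport genes had 1.98 (1.54 to 2.93, percentile 100), 23 of 33 higher, among them argT, dppA and dppB at 6.72, 5.85 and 5.21. Targets reported as repressed had 1.16 (0.02 to 2.70, percentile 100), 14 of 25 higher and 1 lower. These 4 lists were in the highest 2.5% by deposited names as well. Amino acid catabolism genes (median 4.43, -0.22 to 5.68, 6 of 10 higher) and RpoS-dependent genes (median 3.14, 7 of 9 higher, or 2.86 with the 2 members at 0 reads set to their bounds) had percentiles of 100 and 99.8. By deposited names these were 87.8 and 49.7, with medians of 0.56 (9 of 20 higher, 4 lower) and 0.36 (6 of 19 higher, 6 lower). Toxin-antitoxin genes had 2.26 (percentile 98.8, 5 of 7 higher), led by dinJ at 3.10, but stood at 20.1 by deposited names (median -0.23, 5 of 13 higher, 4 lower).

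Of 2164 entries past the filter in RPFs, 733 were at least 2-fold higher and 599 lower, with a median log2 ratio of 0.13. Counting error alone gave a mean of 92.5 higher and 99.1 lower among entries with recovered reads. The mutant RPF library also held many fragments of stable RNA: intervals over tRNA, rRNA and abundant small stable RNA took 19.5% of wild-type RPF reads and 44.0% of mutant RPF reads, which lowers the RPKM of all other mutant genes. Of these 48 intervals 27 are among the compared RPF entries and 31 among those of mRNA. Without them 926 entries were higher and 406 lower, so that higher entries made up 69.5% of those past 2-fold in place of 55.0%; without the 20 highest intervals the share was 62.3%.

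**Figure D2:**
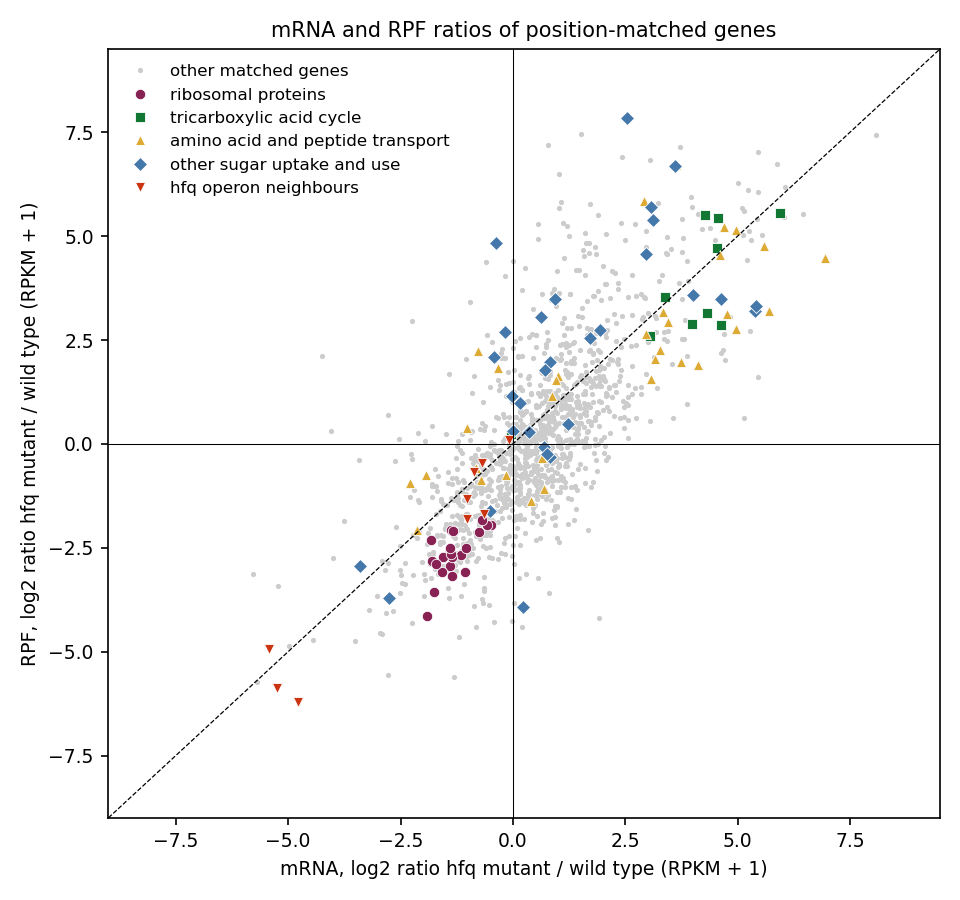
Log2 ratio of the hfq mutant to the wild type (RPKM plus 1) in RPFs against mRNA, 1 point per position-matched gene with a mean of at least 5 RPKM in both assays, with 5 gene lists coloured and the dashed line marking equal ratios. Ribosomal protein genes lie low and below the line, TCA cycle genes high, and several genes of sugar uptake and use above the line.

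Translation efficiency asks whether ribosome density departed from the mRNA level. Intervals on the galactose permease gene galP had far more RPFs per mRNA in the mutant (listed as endA and rsmE, log2 ratios of 5.25 and 5.08): over galP, 1377 wild-type and 482 mutant mRNA reads stood beside 18 and 323 RPF reads. Sorbitol genes srlA with srlE had 5.32, and glycolate oxidase was at least 22.6-fold (glcF with glcE) and at least 7.81-fold (glcD) higher with the floor, which leaves out the counting error of the other reads. The cyuP interval had the highest log2 ratio, 8.41, from 1 and 7 RPF reads (11.7-fold higher in RPFs, 1.51 to 529), and cyuP with cyuA (listed as tdcG) had 5.86 from 8 and 19. The arabinose regulator gene araC had 4.38 from 5 and 71 RPF reads at nearly equal mRNA, lldP (listed as lldR) 4.76 from 5 and 31, and yjfN with aidB (listed as ulaR) 4.75 from 14 and 22. The overlapping genes hokC and mokC had 0 wild-type and 4 or 5 mutant RPF reads and share most of their sequence, so their values are uncertain.

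The lowest translation efficiency ratios included cysI of sulphite reduction (listed as cysJ, log2 ratio -4.51), whose mRNA was 37.3-fold higher (34.0 to 40.9) while RPFs were 1.57-fold higher (0.901 to 2.71), and cysW with cysA of sulphate uptake (listed as cysP, -3.85). The mannitol dehydrogenase gene mtlD (listed as yibL) had -4.17 from 81 and 3 RPF reads (16.1-fold lower in RPFs, 5.31 to 79.7), lysP (listed as yeiE) -4.16 from 61 and 1 (36.4-fold, 6.28 to 1459), fabG of fatty acid synthesis (listed as acpP) -3.58 from 1311 and 37, gpt -3.43 from 193 and 13, and plaP with tsuA (listed as yeeY) -3.42 from 115 and 4. The topA interval (listed as yciX) had -3.83 and potC (listed as potB) -3.35, each with 1 mutant RPF read (11.9-fold lower in RPFs, 1.91 to 494, and 12.5-fold, 2.01 to 518). Intervals on cyaA (listed as yifL) and sfsB (listed as mlaB) had 9 and 11 wild-type and 0 mutant RPF reads. With the floor cyaA is at least 2.47-fold lower, while its RPF ratio alone has a lower limit of 1.18, and the bound for sfsB allows no difference. The interval listed as ymiA, whose reads were not recovered, had -3.30.

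By list, genes of sugar uptake and use (without the maltose system) had the highest position among translation efficiency ratios. Their median log2 ratio was 0.79 (-0.41 to 1.19, percentile 100), with 13 of 31 at least 2-fold higher and 7 lower. With the member at 0 reads set to its bound the median was 0.47, and with intervals lying at least 80% on their gene it was below 0 (-0.32). Beside srlA and galP, mglA had 3.07, while gatC and gatD had -2.19 and -2.10 with mtlD lowest. SOS response genes, which answer DNA damage, had 1.05 (0.14 to 1.35, percentile 99.8), 7 of 13 higher and none lower, with dinB highest, followed by polB at 1.63 and lexA at 1.49. Targets reported as repressed had 0.29 (-0.64 to 0.88, percentile 100), 7 of 25 higher and 3 lower, with srlA, dppA and galK at 5.32, 2.92 and 2.86. Genes for iron-containing enzymes had 0.14 (-1.57 to 0.44, percentile 98.1), with 0 of 11 higher and 4 lower. TCA cycle genes had -0.12 (-1.11 to 0.51, percentile 97.7), with 1 of 10 higher and 3 lower and a median above 0 under each of the 3 other scalings (0.54, 0.36 and 0.33). With 10 expression bins both left the highest 2.5% (97.1 and 96.6). By deposited names TCA cycle genes stood at a percentile of 99.7 and iron-containing enzymes at 96.6. The sugar, SOS and repressed lists stood at 94.9, 94.1 and 96.5 by name. The medians of these 3 lists by name were -0.06 (10 of 35 higher, 11 lower), 0.12 (3 of 17 higher, 3 lower) and -0.08 (11 of 39 higher, 7 lower).

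Respiratory chain and ATP synthase genes had the lowest position, with a median of -1.42 (-1.78 to -1.16, percentile 0.425) and 13 of 17 at least 2-fold lower, among them nuoN at -2.68, nuoL at -2.24 and nuoM at -1.90. Purine and pyrimidine genes had -1.21 (percentile 0.48), 13 of 23 lower, with purF at -3.77 from 20 and 1 RPF reads (11.9-fold lower in RPFs, 1.91 to 494). Small subunit ribosomal protein genes had -1.46 (-1.67 to -1.26, percentile 2.09) and large subunit genes -1.18 (-1.51 to -1.01, percentile 23.2), with 9 of 10 and 9 of 11 lower; rpsQ, rpmJ and rpsC were lowest at -2.22, -2.01 and -1.83. By deposited names the percentiles were 0 for respiration, 4.31 for purines and pyrimidines, 8.44 for the small subunit and 4.68 for the large. The medians of these 4 lists were below 0 under each scaling tried, but their size depends on it. With median-of-ratios scaling the position-matched medians were -0.76, -0.58, -0.80 and -0.52 in the same order, each short of 2-fold. The counts of genes at least 2-fold lower are those of the deposited RPKM. Of translation factors, tufB had 1.87, but its interval takes in tRNA genes and tufB is nearly identical to tufA, so this value is uncertain.

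Of 2111 entries compared in translation efficiency, 343 were at least 2-fold higher and 678 lower, with a median log2 ratio of -0.41; counting error alone gave means of 84.3 and 92.7 among entries with recovered reads. This split turns with the scaling. There were 572 higher and 322 lower with median-of-ratios scaling, 503 and 412 without the 20 highest intervals, and 486 and 432 without the stable RNA intervals, so that higher entries outnumbered lower ones in each of these 3 and made up 33.6% of those past 2-fold in the deposited RPKM.

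**Figure D3:**
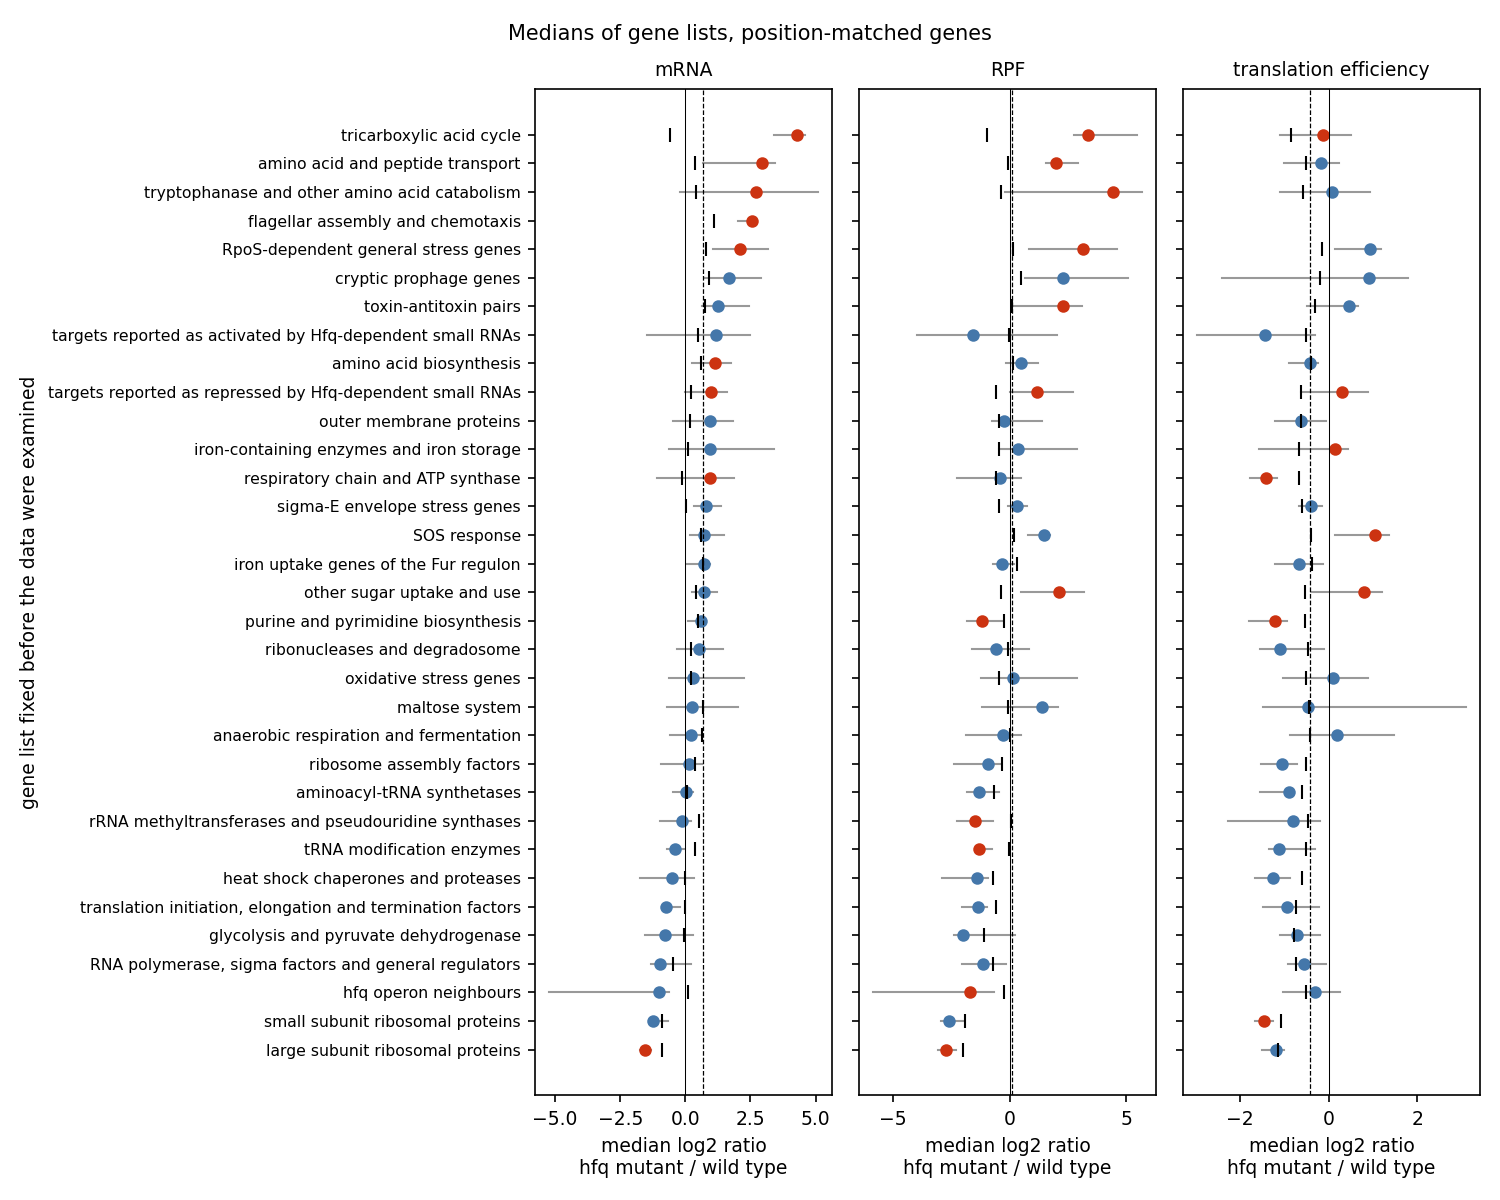
Median log2 ratio of the hfq mutant to the wild type (RPKM plus 1) per gene list in mRNA, RPFs and translation efficiency, with bootstrap 95% intervals over members (lines), the median of expression-matched random lists (ticks) and the median of all matched genes (dashed). Red marks lists in the lowest or highest 2.5% of random lists; TCA cycle genes top mRNA at 4.30 and large subunit ribosomal protein genes close it at -1.55.

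Across the 2111 entries, mRNA and RPF log2 ratios had a Pearson correlation of 0.730 and a Spearman correlation of 0.725, a description over entries that are not independent replicates. Genes such as oppA, sdhA, nrdA and the hfl group had ratios of the same sign in both assays. Within the wild type, RPF and mRNA levels had a Pearson correlation of 0.892, and within the mutant 0.781. The median log2 translation efficiency in the deposited RPKM was -0.67 in the wild type and -1.07 in the mutant. This difference depends on the scaling and is not read as lower translation in the mutant. The median change per entry was -0.41 in the deposited RPKM, but 0.03 without the stable RNA intervals and 0.25 with median-of-ratios scaling. Translation efficiency in one strain had a correlation of 0.431 with that in the other. Of the position-matched lists with at least 5 members, 9 of 33 in mRNA, 12 of 32 in RPFs and 8 of 32 in translation efficiency lay in the lowest or highest 2.5% of random lists. Separate lists of independent genes would be placed there in 5% of cases. These lists share members and hold genes of the same operon, so 5% is not their chance rate. By deposited names the tallies were 13 of 36, 10 of 35 and 4 of 34.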

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

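The totals without tRNA and rRNA intervals, the filter of 64 reads, the position matching with its displacements and its overlap of 80%, and the other scalings of position-matched lists were chosen after the results were seen. The correlation of mRNA and RPF ratios kept its sign throughout (0.647 to 0.816), and none of the 72 highest and lowest ratios was reversed, their size leaving no room for a reversal by a shared factor; 448 of their values stayed within the counting interval and 106 moved (0.5 log2 in place of an interval at 0 or unrecovered reads). Of 525 list extremes and 36 ratios at hfq and its neighbours, those past 2-fold kept their direction except yeaG (-0.37) and intE (-0.33) in translation efficiency with a pseudocount of 10. Of those under 2-fold, 51 of 154 and 7 of 14 changed sign under some setting. Counts past the threshold that moved by over 1.5 times were, with median-of-ratios scaling, 674 higher and 666 lower in mRNA and 572 higher and 322 lower in translation efficiency; without the 20 highest intervals, 412 lower in translation efficiency; and without tRNA and rRNA intervals, 432 lower. With no filter, 1128 were higher in RPF and 579 in translation efficiency, and with a minimum of 20 RPKM 706 were higher in mRNA, 448 in RPF and 194 in translation efficiency. A pseudocount of 10 left 208 higher in translation efficiency. At 3-fold there were 739 higher and 159 lower in mRNA, 391 lower in RPF, and 211 higher and 357 lower in translation efficiency, since a stricter threshold passes fewer entries. At 64 reads there were 211 higher and 377 lower in RPF and 106 higher and 338 lower in translation efficiency. Of list medians, 87 by name and 82 by position moved. Among medians in the highest or lowest 2.5%, the tricarboxylic acid cycle median in translation efficiency was reversed by name with a pseudocount of 10 (-0.0057) and with position matching (-0.12), and by position with median-of-ratios scaling (0.54), without the 20 highest intervals (0.36), with no filter (0.14) and without tRNA and rRNA intervals (0.33). Also reversed were iron uptake by name in RPF without tRNA and rRNA intervals (0.0108) and, with an overlap of 80%, sugar uptake and use in translation efficiency (-0.32) and amino acid catabolism in mRNA (-0.23). Of the other 146 medians, 55 changed sign under some scaling. Apart from the stricter threshold, the cause was not tested. All shares of reads moved without the 20 highest intervals. With 10 expression bins, 6 of 202 list percentiles changed side, among them small subunit genes in RPF, which entered the lowest 2.5%. TMM normalization, planned for deposited counts only, was left out and not tried on the recovered reads. No paired analysis was possible because each group has 1 library and no label pairs them. RPF depth, with a median of 2 reads per entry, limits single-gene RPF and translation efficiency values.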

Other observations

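The tests of all 3 patterns weighed here were chosen after the result was seen, as were the genes singled out. The rule for ribosomal protein genes was extended after its value was known, without a different outcome. Nitrate reductase genes stood far above the wild type in mutant mRNA, with log2 ratios of 5.17 for narI, 5.14 for narJ and 4.76 for narH. In the same list of anaerobic respiration and fermentation genes glpA and glpB had -5.23 and -3.76, and the list's median was 0.20 (percentile 8.30), below 0 with median-of-ratios scaling (-0.47). Genes for RNA polymerase and general regulators had a median of -0.99 in mRNA (percentile 8.85), with rho, rpoB and rpoA at -1.67, -1.59 and -1.52.

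Among stable RNA intervals, the one over leuZ, glyW and cysT (listed as uvrC) took 2.90% of wild-type RPF reads and 10.9% of mutant RPF reads, and the one with leuU (listed as folP) 1.92% and 7.06%. The interval with rrsG (listed as clpB) took 8.75% and 8.47%. All rRNA intervals held 9.06% and 10.0%, but 0.278% and 1.35% without the 20 highest intervals, which include that one. All tRNA intervals held 10.5% and 34.0%. In mRNA, stable RNA intervals held 1.43% of wild-type and 6.54% of mutant reads.

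Many values appear to stand under a neighbouring gene's name. The displacement of 2000 bases was read from these data, and with displacements chosen on other blocks of intervals (700 and 1700 bases) the correlation gained 0.0401 over the named genes (bootstrap -0.00119 to 0.0900). The interval includes 0, so this cannot tell whether intervals came from an assembly version without 2 insertion elements. Reads running on from abundant genes, with names in place, would leave no ribosomal protein label low. Of 52 such labels, 5 lay below the wild-type mRNA median of 6.78 RPKM, which argues against it for these 5 labels only. The cut for this count was set after the result was seen. The displacement stays open, and no biological explanation was tested.

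Ribosomal protein genes had fewer RPFs per mRNA in the mutant. More tRNA and rRNA fragments would lower all genes alike, but the 21 genes lay -0.93 (bootstrap -1.10 to -0.71) below the median of all matched genes. By the cut of 2.5, a percentile of 2.23 among expression-matched lists (1.02 with 10 bins) argues against a trend shared by other abundant genes as the whole cause, but only narrowly. The list median was -1.37 (bootstrap -1.51 to -1.18), random lists had -1.15, and large subunit genes alone were at 23.2. By deposited names small and large subunit genes stood at 8.44 and 4.68, above the cut, and at 3.1 and 1.12 with 10 bins. Such a trend is therefore not excluded. Genes that share an operon are not independent, so the interval is too narrow. The loss of Hfq, the far lower levels of the hfl genes after it, a different growth rate and the cassette's resistance to the chloramphenicol in the lysis buffer stay open as untested. The first 2 occur in the same strain and cannot be told apart here.

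Of 31 genes of sugar uptake and use (without the maltose system), 13 had at least 2-fold more RPFs per mRNA in the mutant and 7 at least 2-fold fewer. Among the 26 with at least 64 RPF reads the median lay 1.46 above that of all such genes (bootstrap -0.12 to 2.93), so an effect of few reads cannot be told apart from a difference in translation, because the interval includes 0. The list's median was also below 0 when intervals had to lie at least 80% on their gene (-0.32), and by deposited names (-0.06). The loss of Hfq and the far lower levels of the hfl genes after it stay open as untested.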
